A study of Mus musculus with 19 samples.

How the data were processed

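The series holds 19 samples of cultured fibroblasts from gonad, heart, kidney, liver, lung, skin and tail of mice 8 to 10 weeks old. Per the labels, tissue pieces of 2 to 3 mm were digested with 0.05% trypsin or 0.5 mg/mL collagenase at 37 °C for 40 min and cultured for 5 days in medium with 10% serum, and 0.1 µg of RNA was labelled with Cy3. Organs were taken as groups from the labels, which name 7, with 3 samples of gonad, heart, liver, lung and tail and 2 of kidney and skin.

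Per the file headers, the authors used Agilent Feature Extraction 11.0.1.1 on a 1-colour mouse design of 62976 spots. The values used are the background-subtracted, spatially detrended spot intensity of 1 array, in scanner units and not normalized between arrays, deposited by the authors. The deposited raw spot intensity and local background intensity are medians over pixels. The deposited flags are of another unit (0 or 1) and mark spots well above background, saturated or non-uniform. The deposited value table also holds an intensity, and it was checked to equal the raw median of all 62976 spots on each of 18 arrays. It was used as an alternative only, and the value for lung replicate 2 comes from it alone.

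Probes were joined to genes by RefSeq accession. Of 55681 biological probes, 27235 had a symbol, for 20660 genes. Spots with outlier or saturation flags were set to missing (2023 probe values), log2 of the intensity less each array's 75th percentile was taken, and the probe of each gene with the highest mean was kept if it had no missing value and was well above background on at least 2 arrays. This left 19708 genes, with 463 left out as dim and 489 without a complete probe. The share of probes well above background per array measures the depth, as given in the report.

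Limma 3.58.1 in R 4.3.3 fitted 7 organ means (11 residual degrees of freedom), with 9 contrasts, an F test over organs and the genes higher in 1 organ than in each of the other 6 over 21 organ pairs. P-values were adjusted by Benjamini-Hochberg within each contrast. The 33 gene lists were written before the data were examined and tested with camera (correlation 0.01), adjusted over all list tests. Named genes follow a rule fixed beforehand: for each contrast, the 10 largest higher and 5 largest lower genes past the threshold in which every array of the named side lies beyond every other array, without predicted or clone names, plus the 4 largest passing members of each described list, the Hox genes and 5 sex genes. The report prints those of them with a described function, a choice made after their values were seen. Which list results are described singly was also chosen after seeing them, and some genes that the rule gives are not described. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures. In simulated data 200 of 19708 genes were shifted by 1.5 to 4 log2. By camera a list of 17 shifted by 2 passed (adjusted p = 6.1e-38) and 0 others. False list calls in real data stay untested.

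Alternatives tried were normexp (offset 50, on the raw medians, since mean spot signal was not given in the sources used here) with quantile normalization, quantile normalization, median scaling, other filters on dim probes, the mean of a gene's probes, a variance trend with robust eBayes, array weights (whose fit did not fully converge), the slide and the replicate number as blocks, the value table, other thresholds, leaving out each array, pooling all other arrays, an estimated correlation in camera and fry. Chosen after seeing the data were leaving out or keeping only the 5 high-background arrays, and their membership or the array floor as a term. Kidney has no array among the other 13. Within-slide values use the organs on that slide, and their genes were called on all slides together. Probes without a symbol were left out.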

Results

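Fibroblasts grown out of 7 adult mouse organs were profiled on 1-colour expression arrays, and the comparisons below ask how far cells cultured under the same conditions still differed by their organ of origin. There were 3 samples each of gonad, heart, liver, lung and tail and 2 each of kidney and skin, 19 in all. The scanner output of lung replicate 2 was not given in the sources used here, so 18 arrays entered the comparisons. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between samples. The number of arrays limits the precision of every value.

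The arrays differed in signal from genes at the floor. The control spots that should stay dark read above the scanner software's accepted range on gonad 3, heart 1, kidney 1, kidney 2 and tail 2, called here the 5 high-background arrays. Their median raw spot signal was 213 to 1985, against 63 to 130.5 on the 13 other arrays. The share of probes well above background was 90.8%, 95.4%, 96.3%, 89.1% and 84.8%, against 50.1% to 76.9%. Both kidney arrays are among the 5, so the kidney comparison cannot be made on the other 13.

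**Figure D1:**
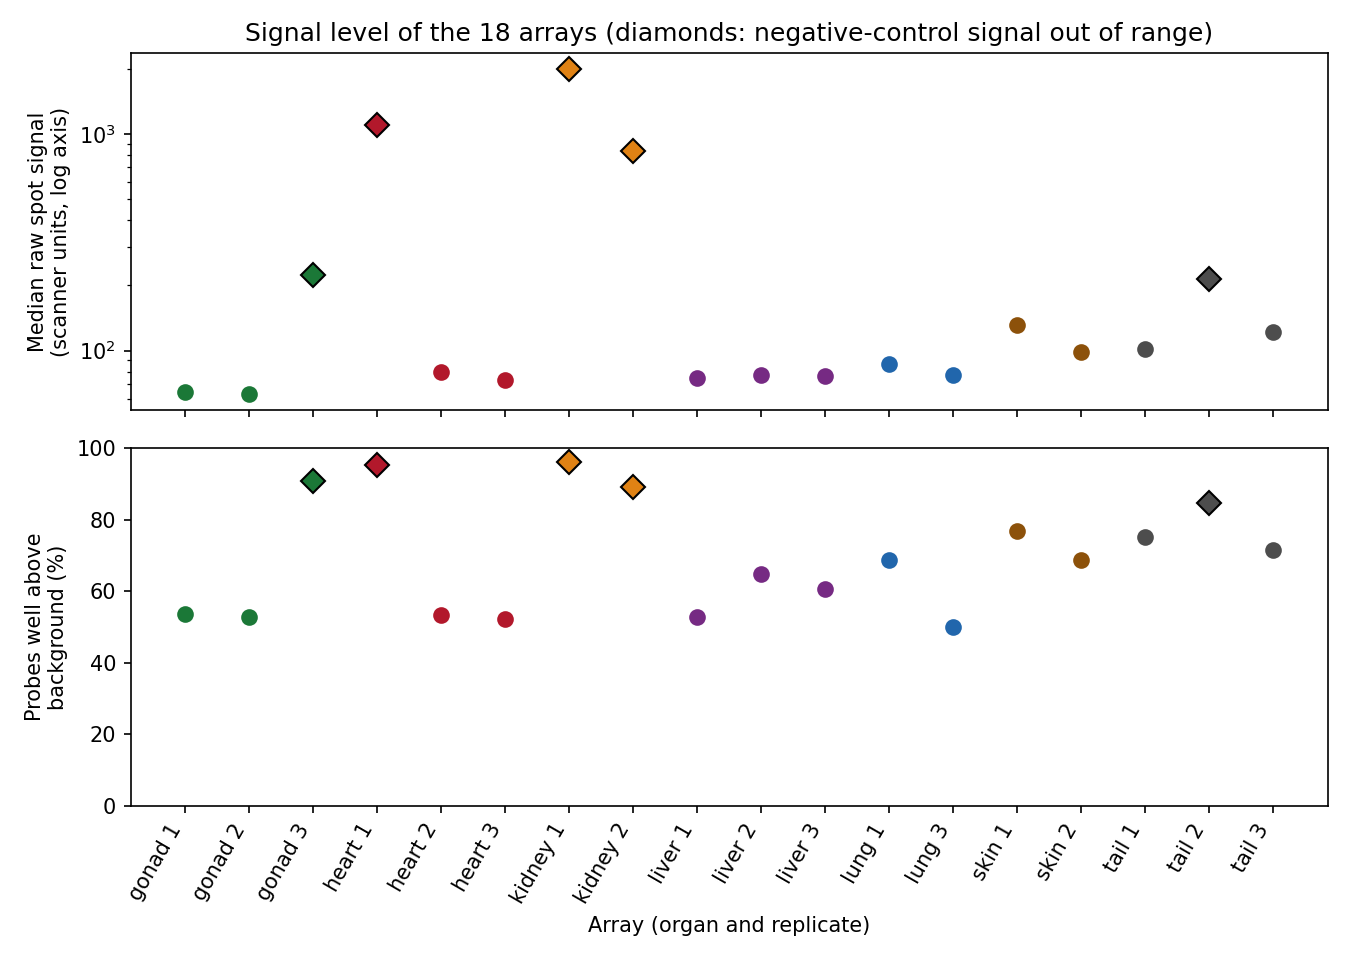
Median raw spot signal (log axis, scanner units) and percent of probes well above background for each of the 18 arrays, grouped by organ, with diamonds for the 5 arrays whose dark control spots read out of range. The 5 arrays lie between 84.8% and 96.3% of probes and the 13 others between 50.1% and 76.9%.

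In each comparison below, an organ mean is set against the unweighted mean of the other organ means. Fold changes are log2 values ± SE from limma, and a gene passed with an adjusted p under 0.05 and a log2 change of at least 1. Where at least 1 organ of the lower side lay at background, the change is given as a lower bound ("at least N-fold") on the scale of these signals. Normexp, with its offset, and the floor covariate gave less for some genes. No bound is given in kidney, whose raised floor would inflate it. The median shift of all genes was -0.06 for gonad, -0.11 for heart, -0.36 for kidney, 0.12 for liver, 0.08 for lung, 0.38 for skin, 0.34 for tail, 0.01 for skin against tail and 0.45 for skin and tail against the 5 internal organs. With normexp and quantile normalization it moved to -0.19 for kidney, 0.01 for skin, 0.03 for skin and tail against the internal organs and -0.0035 for tail. Scaling to the median of detected probes moved it to -0.64 for kidney, 0.23 for liver and 0.24 for lung. Single genes are given as fitted, and gene lists by their relative median, the list's median log2 difference less that of all genes. Counts of members within the list are adjusted over it alone, and a median moves where leaving out 1 array changes it by more than 1.5 times. A call is described as lost where a gene or list no longer passed under an alternative. These are quantile scaling (quantile normalization), median scaling (to the median of detected probes), mean of probes (averaging a gene's probes), no dim filter, the value table (the 19 samples of the deposited table), the slide block (slide as a term), normexp (normexp background correction and quantile normalization), 13 arrays (without the 5 high-background arrays, and so without kidney, which sets an organ against 5 others and skin and tail against 4), the background term (membership of the 5 as a term) and the floor covariate (each array's floor as a covariate). Calls lost with a stricter threshold, with the replicate number as a block, with only probes well above background on all arrays, or with all other arrays pooled as one group (182 gene calls) are not marked gene by gene. List results not given singly are counted at the end. The followed genes are those the naming rule gave. All arrays of the named side lay on the stated side of the other side's mean in each of them. The rule selects on these same arrays and largely fixes this, so it is no separate check.

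Organ of origin separated the samples in most cases. By correlation across genes, which are not independent replicates, 15 of 18 arrays lay nearest to another array of their own organ. The exceptions were gonad 3, heart 1 and liver 3, of which the first 2 are high-background arrays. Limma's moderated F test found 6696 of 19708 genes different among the 7 organs, 4384 with the slide block and 8250 on the 13 arrays with normexp, which hold 6 organs. Among pairs of organs without kidney, changed genes ran from 7 between liver and lung to 1063 between gonad and tail. In all, 286 genes were higher in 1 organ than in each of the other 6: 142 in kidney, 82 in tail, 29 in gonad, 19 in heart, 14 in skin and 0 in liver and lung. By limma at an unadjusted p under 0.05 these were 591, 210, 81, 70, 63, 28 and 20. On the 13 arrays with normexp, where without kidney a gene has to be higher than in only 5 other organs, they were 204 in tail, 161 in gonad, 150 in heart, 107 in skin, 15 in lung and 4 in liver, with 73, 29, 18, 14, 0 and 0 shared. The kidney count was 1174 with normexp, 30 with the floor covariate, 15 with the background term, and 0 by limma without kidney 1 (117 at an unadjusted p under 0.05). The total ran from 53 without skin 2 to 1835 without heart 1, and the F test count from 1797 without kidney 1 to 16081 without heart 1.

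Hox genes, the homeobox regulators that record position along the body axis, set several organs apart. Of 36 Hox genes measured, 9 were detected on all heart arrays, 19 on all lung, 23 on all liver, 29 on all tail, 31 on all gonad, 34 on all skin and 35 on all kidney arrays, the last on high-background arrays only. In heart, 17 were lower than in the other organs, led by Hoxb6 (log2 -7.08 ± 0.44, adjusted p = 8.6e-07), Hoxb7 (log2 -6.99 ± 0.44, adjusted p = 8.6e-07) and Hoxc6 (log2 -6.41 ± 0.58, adjusted p = 3.1e-05). In tail Hoxb13 (at least 1509.8-fold higher, adjusted p = 4.3e-06), Hoxc13 (log2 5.17 ± 0.43, adjusted p = 9.4e-06) and Hoxc11 (at least 25.3-fold higher, adjusted p = 0.0019) were higher, and the anterior Hoxa3 (log2 -2.70 ± 0.32, adjusted p = 1.3e-04) and Hoxa4 (log2 -2.36 ± 0.56, adjusted p = 0.020) were lower. The anterior gene Hoxa3 was higher in liver (log2 3.14 ± 0.32, adjusted p = 3.9e-04) and in lung (log2 3.41 ± 0.38, adjusted p = 0.0013, lost with quantile scaling). In liver the posterior Hoxc9 (log2 -5.29 ± 0.84, adjusted p = 0.0050) and Hoxa10 (at least 7.21-fold lower, adjusted p = 0.0066, lost with quantile scaling) were lower, and so were Hoxa10 (at least 5.80-fold lower, adjusted p = 0.043, lost with normexp, quantile scaling, 13 arrays and 13 arrays and normexp) and Hoxc13 (log2 -3.25 ± 0.51, adjusted p = 0.012) in lung. Skin had higher Hoxc9 (log2 5.56 ± 0.99, adjusted p = 0.013), Hoxb9 (log2 4.09 ± 0.74, adjusted p = 0.013) and Hoxc6 (log2 4.14 ± 0.69, adjusted p = 0.0089). Gonad had higher Hoxd9 (at least 18.2-fold higher, adjusted p = 0.010), Hoxd10 (log2 4.22 ± 0.94, adjusted p = 0.025) and Hoxc6 (log2 3.60 ± 0.58, adjusted p = 0.0031). As lists, Hox groups 1 to 4 gave these counts. In heart, 0 of 12 were higher and 7 lower (0 and 9 within the list). The list's relative median was -2.19, with adjusted p = 2.2e-14 and adjusted p = 0.0076 with an estimated correlation. In liver, 5 of 12 were higher and 0 lower (7 and 0 within the list). The relative median was 1.25, with adjusted p = 1.5e-04 and adjusted p = 0.060 with an estimated correlation. In lung, 4 of 12 were higher and 0 lower (6 and 1 within the list). As a group they had a relative median of 1.28, with adjusted p = 4.2e-04 and adjusted p = 0.083 with an estimated correlation. In tail, 0 of 12 were higher and 2 lower (0 and 3 within the list). Together their relative median was -1.14, with adjusted p = 9.2e-07 and adjusted p = 0.035 with an estimated correlation. Of Hox groups 5 to 8 in heart, 0 of 10 were higher and 7 lower (0 and 7 within the list). Over the list, the relative median was -4.13, with adjusted p = 2.1e-18 and adjusted p = 0.035 with an estimated correlation.

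**Figure D2:**
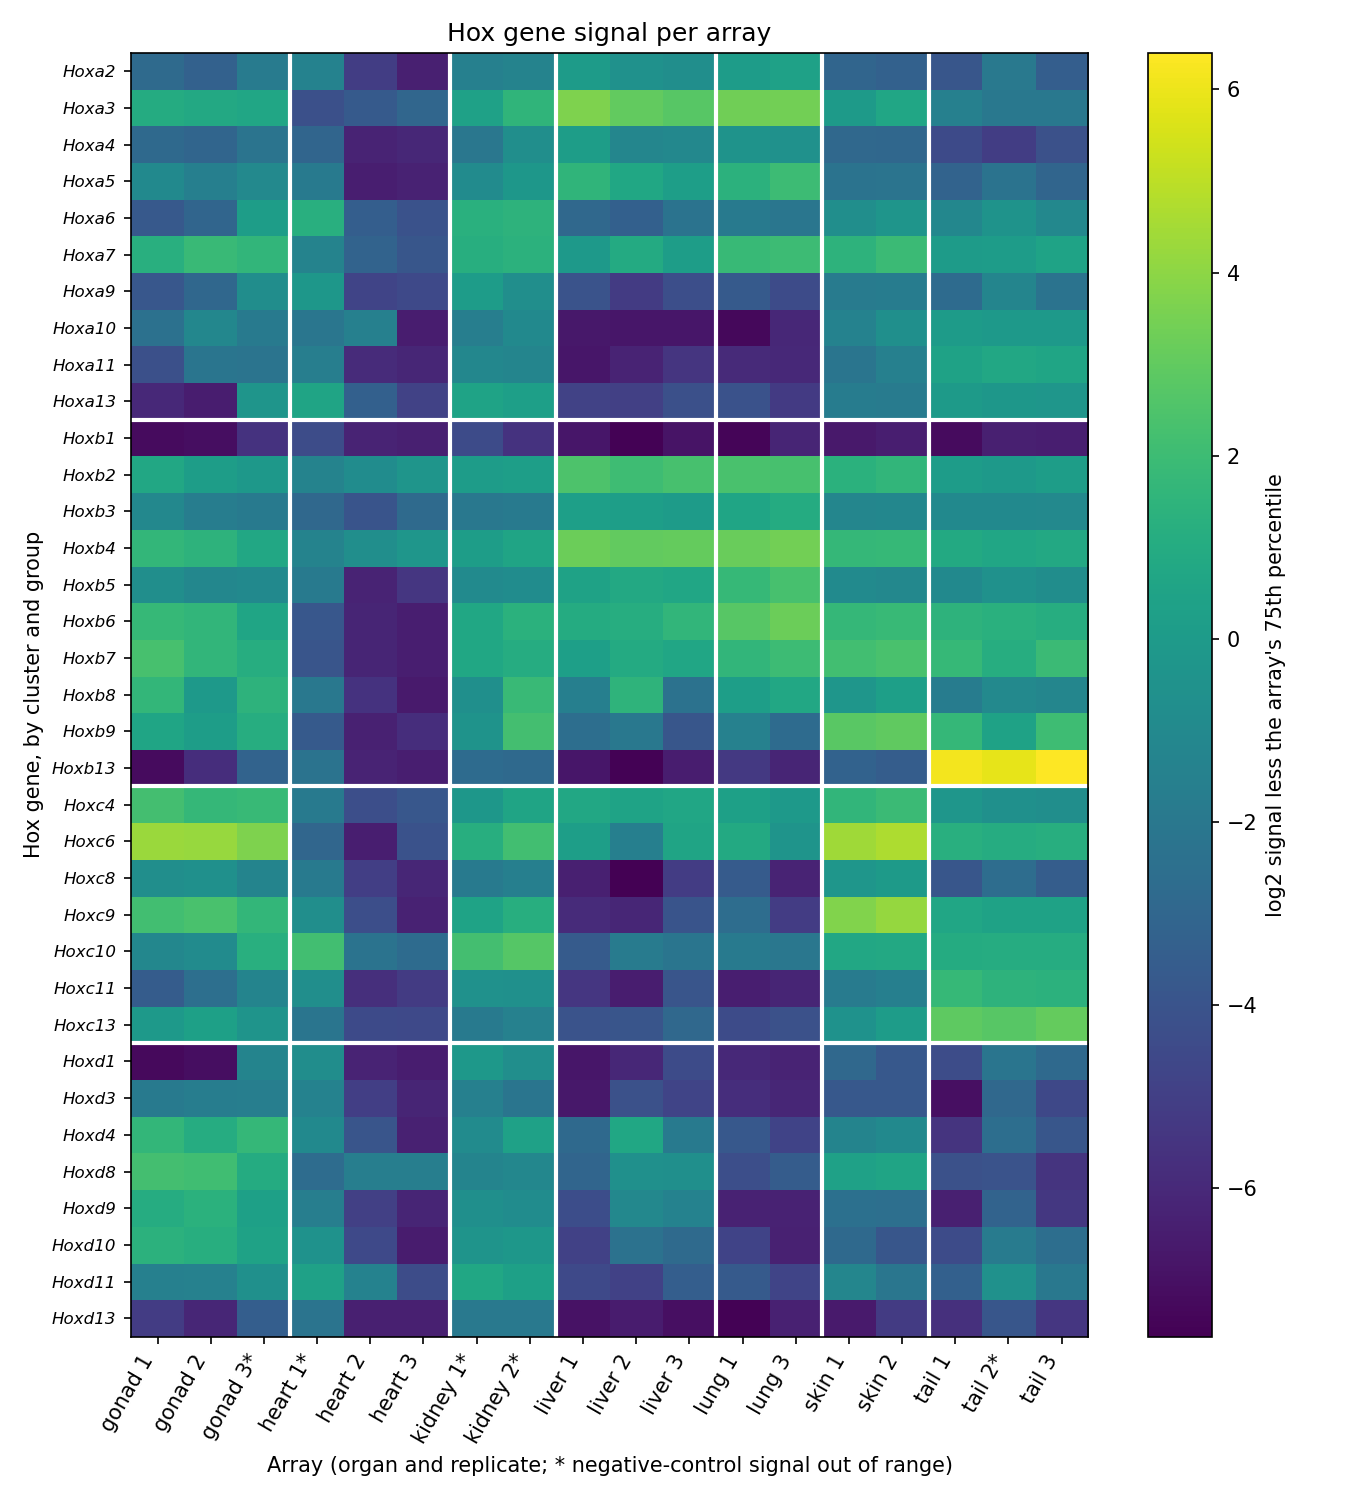
Heat map of 35 Hox genes (one per line, by cluster and group) on 18 arrays (columns, grouped by organ), coloured by log2 signal relative to the array's 75th percentile, with asterisks on the 5 high-background arrays. In tail Hoxb13 is at least 1509.8-fold higher, adjusted p = 4.3e-06, and Hoxb6 (log2 -7.08 ± 0.44, adjusted p = 8.6e-07) is lower in heart than in the other organs.

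Hox groups 9 to 13, the posterior end of the clusters, passed as a list in tail, liver, lung, heart, gonad and skin. Of 14 genes, 6, 0, 0, 0, 4 and 2 were higher in that order (7, 0, 0, 0, 4 and 3 within the list) and 0, 5, 2, 3, 0 and 0 lower (1, 12, 9, 3, 1 and 0 within the list). The relative medians were 1.62, -2.68, -3.13, -1.33, 0.76 and 0.69, with adjusted p = 2.1e-04, 9.3e-08, 2.0e-11, 2.1e-04, 0.0082 and 0.041, and adjusted p = 0.55, 0.33, 0.18, 0.55, 0.68 and 0.73 with an estimated correlation. The skin result was also lost with normexp, quantile scaling, no dim filter, the slide block, the value table and the floor covariate. On heart 1 the heart result lay the other way (1.72 from the mean of the 7 organs, as in all such remarks), the median moving to -3.00 without heart 1 and -0.27 without heart 3. In gonad it moved to 0.35 without gonad 3. In gonad, Hoxc9 (log2 3.32 ± 0.84, adjusted p = 0.049, lost with mean of probes) and Hoxc13 (log2 1.70 ± 0.43, adjusted p = 0.049, lost with normexp and 13 arrays and normexp) were higher.

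Gonad fibroblasts (n = 3 arrays against 15) differed from the other organs in 573 genes, 414 higher and 159 lower. Nr5a1, the nuclear receptor that switches on steroid synthesis genes, was higher at log2 5.53 ± 0.41, adjusted p = 1.7e-05. Also higher were Aard (at least 110.5-fold higher, adjusted p = 4.1e-05) and Acsbg1 (at least 103-fold higher, adjusted p = 7.7e-05), Prss35 (log2 5.96 ± 0.49, adjusted p = 3.8e-05) and Tesc (log2 5.85 ± 0.61, adjusted p = 1.5e-04), and Clic5 (at least 43.3-fold higher, adjusted p = 2.7e-04) and Casq2 (log2 5.61 ± 0.78, adjusted p = 0.0010), of which Casq2 binds calcium in muscle stores. The protease Mmp3 (log2 -5.89 ± 0.93, adjusted p = 0.0025), Lrrc17 (log2 -4.41 ± 0.52, adjusted p = 3.0e-04) and Evi2a (log2 -4.05 ± 0.51, adjusted p = 4.5e-04) were lower.

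Of the gonad somatic genes, 7 of 19 were higher and 0 lower (9 and 0 within the list). As a whole, their relative median was 0.70, with adjusted p = 5.5e-10 and adjusted p = 0.012 with an estimated correlation, the median moving to 1.09 without gonad 3. They included Nr5a1, Gata4 (at least 23.0-fold higher, adjusted p = 6.2e-05), a zinc finger regulator of gonad development, the anti-Müllerian hormone receptor Amhr2 (log2 4.83 ± 0.61, adjusted p = 5.1e-04), and Wt1 (log2 4.45 ± 0.55, adjusted p = 4.5e-04). Of the contractile and smooth muscle genes, 5 of 14 were higher and 0 lower (10 and 0 within the list). Across the list, the relative median was 1.60, with adjusted p = 3.1e-13 and adjusted p = 0.052 with an estimated correlation. Among these were the myosin kinase Mylk (log2 3.44 ± 0.30, adjusted p = 3.8e-05) and the smooth muscle myosin Myh11 (log2 3.29 ± 0.44, adjusted p = 8.6e-04). Markers of other cell types moved too. Of the endothelial markers, 6 of 16 were higher and 0 lower (7 and 0 within the list). In all, their relative median was 1.62, with adjusted p = 4.8e-08 and adjusted p = 0.19 with an estimated correlation. The vascular cadherin Cdh5 (log2 4.14 ± 0.56, adjusted p = 8.6e-04) and Emcn (log2 3.86 ± 0.67, adjusted p = 0.0048) were among them. Of the mesothelial and epicardial markers, 2 of 12 were higher and 0 lower (5 and 1 within the list). Their relative median was 1.37, with adjusted p = 2.1e-04 and adjusted p = 0.25 with an estimated correlation, the median moving to 0.87 without gonad 2. Wt1 and Gpm6a (at least 7.29-fold higher, adjusted p = 2.5e-04) were the higher ones. Of the chemokines and cytokines, 1 of 20 were higher and 5 lower (1 and 7 within the list). The list's relative median was -1.0, with adjusted p = 6.4e-05 and adjusted p = 0.12 with an estimated correlation, the median moving to -0.57 without gonad 1 and -1.90 without gonad 3. The neutrophil attractant Cxcl5 (log2 -7.76 ± 1.06, adjusted p = 9.5e-04) and Ccl8 (log2 -3.40 ± 0.65, adjusted p = 0.010) were lower and Cxcl14 (log2 4.33 ± 0.51, adjusted p = 2.8e-04) higher. Of the interferon-stimulated genes, 0 of 17 were higher and 1 lower (0 and 10 within the list). The relative median was -1.22, with adjusted p = 6.5e-08 and adjusted p = 0.42 with an estimated correlation. Oas1a (log2 -4.40 ± 0.66, adjusted p = 0.0018) was the passing one.

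In gonad, 72.3% of the calls were higher, against 20.1% with 13 arrays, 61.9% with 13 arrays and normexp, 36.8% with the background term, 61.4% with the floor covariate, 16.4% with array weights, 88.9% with all other arrays pooled and 24.0% without gonad 3. For gonad, the slide block gave 527 genes, 499 of them shared. Of the 573 genes, 573, 573 and 571 kept direction on slides 1, 2 and 3. In gonad, 980 passed on the 13 arrays with normexp, 501 of them shared in direction and 0 opposite. Without gonad 1, gonad 2, gonad 3 and heart 1, the count was 213, 225, 2534 and 1130. Of the 38 followed genes, 10, 13, 0 and 0 then lost the call (at most 5 without any other array). The germ cell markers lost the list call without gonad 1, gonad 2 or heart 1 and the Hox groups 9 to 13 lost the list call without gonad 3.

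**Figure D3:**
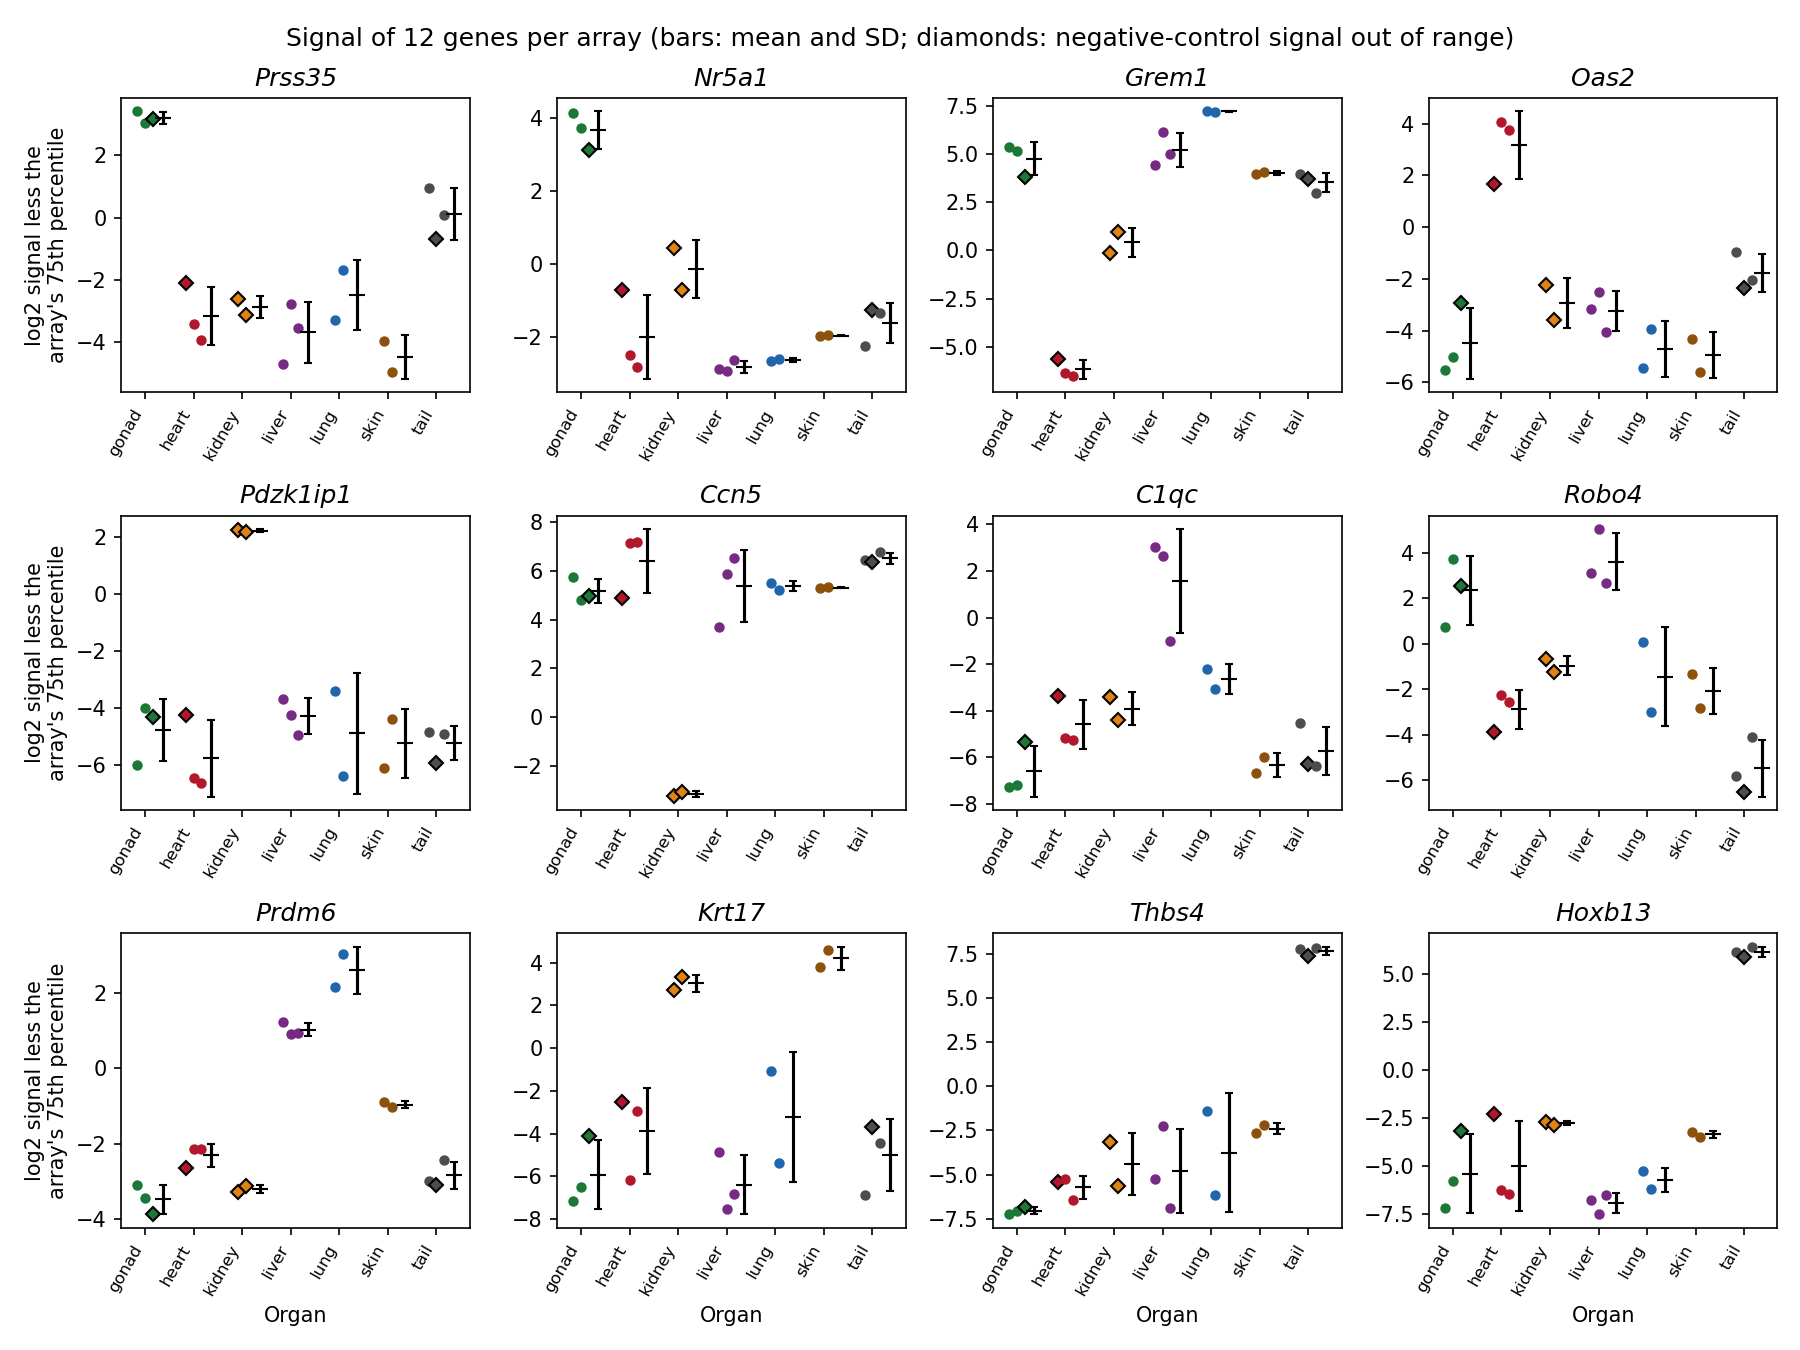
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 genes named in the comparisons, on each of 18 arrays (points) by organ (horizontal axis), with the organ mean and SD as bars. In gonad Prss35 is higher at log2 5.96 ± 0.49, adjusted p = 3.8e-05, in heart Grem1 is at least 455-fold lower, adjusted p = 1.4e-08, and in tail Thbs4 is at least 3670.0-fold higher, adjusted p = 4.3e-06.

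Heart fibroblasts (n = 3 arrays against 15) differed in 742 genes, 270 higher and 472 lower. Interferon-stimulated genes rose together: of this list, 17 of 17 were higher and 0 lower (17 and 0 within the list). As a group they had a relative median of 4.22, with adjusted p = 7.7e-50 and adjusted p = 0.035 with an estimated correlation. Among them were the oligoadenylate synthetases Oas2 (at least 114-fold higher, adjusted p = 3.4e-05) and Oas1a (log2 5.89 ± 0.66, adjusted p = 1.4e-04), the ISG15 protease Usp18 (log2 5.20 ± 0.49, adjusted p = 3.6e-05) and Ifit3 (log2 5.18 ± 0.53, adjusted p = 7.1e-05). Within slides the list's median was 4.81, 3.34 and 4.38 on slides 1, 2 and 3. The secreted BMP antagonist Grem1 (at least 455-fold lower, adjusted p = 1.4e-08) was lower, as were the peptide hormone gene Cck (log2 -8.24 ± 0.48, adjusted p = 4.2e-07) and the interleukin-33 receptor Il1rl1 (at least 36.9-fold lower, adjusted p = 2.2e-07).

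Other genes higher in heart were the cartilage collagen Col2a1 (log2 5.22 ± 0.61, adjusted p = 1.8e-04), Rhox5 (log2 5.06 ± 0.46, adjusted p = 3.1e-05), the glucocorticoid-activating enzyme Hsd11b1 (log2 5.06 ± 0.63, adjusted p = 3.0e-04), and Fndc1 (log2 4.89 ± 0.45, adjusted p = 3.3e-05). Of the heart development regulators, 3 of 13 were higher and 1 lower (4 and 1 within the list). Together their relative median was 0.46, with adjusted p = 0.0084 and adjusted p = 0.18 with an estimated correlation, lost with normexp, 13 arrays and 13 arrays and normexp, and opposite on heart 2 (-0.09) and heart 3 (-0.16), the median moving to 0.02 without heart 1 and 0.91 without heart 2. The cardiac factors Tbx20 (log2 4.38 ± 0.80, adjusted p = 0.0053), Gata4 (at least 12.1-fold higher, adjusted p = 1.5e-04) and Nkx2-5 (at least 4.35-fold higher, adjusted p = 0.0061, lost with normexp and quantile scaling) were higher and Tbx3 (log2 -3.38 ± 0.28, adjusted p = 1.4e-05, lost with the value table) lower. Of the fibroblast markers, 3 of 19 were higher and 0 lower (5 and 0 within the list). Over the list, the relative median was 0.94, with adjusted p = 1.4e-06 and adjusted p = 0.46 with an estimated correlation, and opposite on heart 1 (-0.73), the median moving to 0.58 without heart 2. Tcf21 (log2 4.60 ± 0.51, adjusted p = 1.3e-04), a factor of epicardium-derived fibroblasts, and the proteoglycan Lum (log2 4.28 ± 0.67, adjusted p = 0.0019) were among them. Of the contractile and smooth muscle genes, 0 of 14 were higher and 6 lower (0 and 9 within the list). As a whole, their relative median was -1.51, with adjusted p = 7.6e-14 and adjusted p = 0.046 with an estimated correlation, the median moving to -0.99 without heart 1. They included the actin Actg2 (log2 -5.30 ± 0.43, adjusted p = 1.1e-05), calponin Cnn1 (log2 -4.78 ± 0.41, adjusted p = 1.7e-05), and Myh11 (log2 -4.09 ± 0.44, adjusted p = 1.0e-04). The Wnt antagonist Frzb (log2 4.49 ± 0.44, adjusted p = 4.5e-05) was higher and Dkk2 (log2 -3.16 ± 0.49, adjusted p = 0.0016) lower.

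Among markers of other cell types in heart, of the mesothelial and epicardial markers 1 of 12 were higher and 5 lower (3 and 7 within the list). Across the list, the relative median was -2.39, with adjusted p = 0.0012 and adjusted p = 0.34 with an estimated correlation, lost with 13 arrays and 13 arrays and normexp. Of the endothelial markers, 1 of 16 were higher and 3 lower (2 and 7 within the list). In all, their relative median was -1.08, with adjusted p = 2.5e-04 and adjusted p = 0.45 with an estimated correlation, the median moving to -1.68 without heart 1. Sox18 (log2 -3.52 ± 0.61, adjusted p = 0.0034) was lower and Tek (log2 1.87 ± 0.45, adjusted p = 0.031, lost with normexp) higher. Of the leukocyte and macrophage markers, 0 of 16 were higher and 1 lower (0 and 1 within the list). Their relative median was -0.81, with adjusted p = 0.018 and adjusted p = 0.70 with an estimated correlation, lost with 13 arrays and normexp and the floor covariate, and opposite on heart 1 (1.01), the median moving to -1.72 without heart 1, -0.33 without heart 2 and -0.40 without heart 3. Cd14 (log2 -1.68 ± 0.39, adjusted p = 0.026) was the lower one. Of the cardiomyocyte markers, 0 of 14 were higher and 1 lower (0 and 2 within the list). The list's relative median was 0.00, with adjusted p = 0.20. Actc1 (at least 4.87-fold lower, adjusted p = 1.1e-04) was the lower one. In heart, 36.4% of the calls were higher, against 47.9% with 13 arrays and normexp, 48.0% with all other arrays pooled and 53.5% without heart 1. For heart, the slide block gave 662 genes, 654 of them shared. Of the 742 genes, 742, 710 and 740 kept direction on slides 1, 2 and 3. In heart, 1000 passed on the 13 arrays with normexp, 626 of them shared in direction and 0 opposite. Without heart 1, heart 2 and heart 3, the count was 2068, 463 and 448. Of the 59 followed genes, 0, 14 and 15 then lost the call (at most 6 without any other array). The heart development regulators lost the list call without heart 1, the complement genes lost the list call without heart 1 or liver 3 and the Hox groups 9 to 13, the leukocyte and macrophage markers and the Wnt ligands and antagonists lost the list call without heart 2 or heart 3.

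Kidney fibroblasts (n = 2 arrays against 16) cannot be set against arrays of like background from every organ, and 15334 genes passed, 6986 higher and 8348 lower. With the background term 3008 passed, and among the 5 high-background arrays alone 358, a fit in which the spread pooled over genes gives every gene an SE of 0.79. In all 3 fits 75 genes were higher and 222 lower. The genes named next passed in all 3 and are given from the 5 arrays alone, where kidney is set against gonad 3, heart 1 and tail 2. Among the first were the tubule genes Cdh16 (log2 5.50, adjusted p = 5.3e-09), a kidney cadherin, Pdzk1ip1 (log2 7.05, adjusted p = 2.2e-15), and Pax8 (log2 4.56, adjusted p = 5.2e-06), a nephron lineage factor. The platelet chemokine Ppbp (log2 5.85, adjusted p = 3.2e-10) and Akr1c19 (log2 4.68, adjusted p = 2.6e-06) were also higher. Matrix genes were among the lower ones, with Ccn5 (log2 -8.54, adjusted p = 4.5e-23), the extracellular superoxide dismutase Sod3 (log2 -5.81, adjusted p = 3.8e-10), and the collagen VI chains Col6a1 (log2 -5.46, adjusted p = 6.7e-09) and Col6a2 (log2 -5.54, adjusted p = 4.0e-09).

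Of the fibroblast markers in kidney, 0 of 19 were higher and 15 lower (0 and 15 within the list). The relative median was -2.44, with adjusted p = 1.5e-04 and adjusted p = 0.60 with an estimated correlation, and 7 were lower in all 3 fits. The proteoglycans Lum (log2 -5.54 ± 0.80, adjusted p = 8.3e-04) and Dcn (log2 -5.38 ± 0.62, adjusted p = 3.5e-04) were among them. Of the collagens, 0 of 19 were higher and 14 lower (0 and 14 within the list). As a group they had a relative median of -2.33, with adjusted p = 3.3e-04 and adjusted p = 0.59 with an estimated correlation, and 7 were lower in all 3 fits. Of the simple epithelial markers, 13 of 14 were higher and 0 lower (13 and 0 within the list). Together their relative median was 4.29, with adjusted p = 4.8e-05 and adjusted p = 0.46 with an estimated correlation, and 3 were higher in all 3 fits. They included the keratins Krt8 (log2 4.80 ± 0.94, adjusted p = 0.0019) and Krt18 (log2 4.38 ± 0.75, adjusted p = 0.0014) and the claudins Cldn7 (log2 4.50 ± 0.45, adjusted p = 2.0e-04) and Cldn4 (log2 4.65 ± 1.47, adjusted p = 0.014, lost with the background term, the floor covariate and the 5 arrays alone). Of the kidney tubule markers, 8 of 14 were higher and 1 lower (8 and 1 within the list). Over the list, the relative median was 2.55, with adjusted p = 0.014 and adjusted p = 0.46 with an estimated correlation, lost with normexp and quantile scaling, the list's own median going from 2.20 to -0.03 with normexp, and 1 was higher in all 3 fits. Of the kidney development regulators, 4 of 14 were higher and 4 lower (4 and 4 within the list). As a whole, their relative median was 0.69, with adjusted p = 0.49.

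Of all genes tested, 6986 of 19708 were higher on the kidney arrays and 8348 lower. Markers of other organs and cell types that were higher numbered 11 of 13 germ cell markers, 10 of 15 hepatocyte markers, 10 of 13 lung epithelial markers, 8 of 14 cardiomyocyte markers, 9 of 15 skeletal muscle markers, 9 of 13 keratinocyte markers, 6 of 12 adipocyte markers, 6 of 12 Schwann, neural crest and melanocyte markers and 1 of 9 pericyte markers, and 0, 1, 2, 1, 0, 2, 3, 2 and 4 in that order were lower. Their list tests gave adjusted p = 0.0027, 0.043, 0.057, 0.021, 0.011, 0.059, 0.36, 0.19 and 0.84 in that order, and adjusted p = 0.67, 0.66, 0.69, 0.66, 0.65, 0.65, 0.73, 0.70 and 0.91 with an estimated correlation. Among the 5 arrays alone the same lists had 0, 0, 0, 0, 0, 1, 0, 0 and 0 higher members. Hox genes higher on the kidney arrays were not so in all 3 fits and are not described. In kidney, 45.6% of the calls were higher, against 31.1% with normexp, 7.91% with the background term, 7.96% with the floor covariate, 9.71% with only probes bright on all arrays, 12.3% without kidney 1 and 18.3% without kidney 2. For kidney, the slide block gave 15322 genes, 14955 of them shared. Of the 15334 genes, 15334 and 15333 kept direction on slides 1 and 3. Without kidney 1 and kidney 2, the count was 415 and 8893. Of the 28 followed genes, 9 and 2 then lost the call (at most 0 without any other array). The hepatocyte markers lost the list call without kidney 2.

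Liver fibroblasts (n = 3 arrays against 15) differed in 358 genes, 238 higher and 120 lower. The macrophage complement subunits C1qc (at least 63.7-fold higher, adjusted p = 9.0e-04) and C1qa (log2 5.20 ± 1.05, adjusted p = 0.021) were higher, and so were the leukocyte gene Lcp1 (log2 3.36 ± 0.53, adjusted p = 0.0053), the lipid carrier Apoe (log2 3.46 ± 0.41, adjusted p = 9.2e-04), and endothelial nitric oxide synthase Nos3 (log2 3.59 ± 0.55, adjusted p = 0.0040). The endoderm factor Foxa2 (at least 9.42-fold higher, adjusted p = 9.0e-04) and the signalling protein Wnt4 (log2 3.62 ± 0.44, adjusted p = 0.0011) were higher as well. St8sia2 (at least 5.28-fold lower, adjusted p = 0.023), Wfdc18 (log2 -3.30 ± 0.53, adjusted p = 0.0057) and Etnk2 (log2 -3.00 ± 0.40, adjusted p = 0.0018, lost with normexp) were lower.

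Of the endothelial markers, 7 of 16 were higher and 0 lower (12 and 0 within the list). Across the list, the relative median was 2.42, with adjusted p = 2.0e-10 and adjusted p = 0.15 with an estimated correlation. Robo4 (at least 37.4-fold higher, adjusted p = 0.0024), Tie1 (at least 23.0-fold higher, adjusted p = 0.020) and Cdh5 (log2 4.06 ± 0.56, adjusted p = 0.0021) were among them. Of the leukocyte and macrophage markers, 6 of 16 were higher and 0 lower (11 and 0 within the list). In all, their relative median was 2.61, with adjusted p = 7.1e-08 and adjusted p = 0.32 with an estimated correlation. Ctss (at least 29.1-fold higher, adjusted p = 0.0068) and Mrc1 (at least 7.79-fold higher, adjusted p = 0.028) were among them. This list's median lay 3.96, 3.10 and 0.15 above the mean of the 7 organs in liver 1, 2 and 3. Of the mesothelial and epicardial markers, 6 of 12 were higher and 0 lower (6 and 0 within the list). Their relative median was 2.34, with adjusted p = 2.7e-05 and adjusted p = 0.18 with an estimated correlation, the median moving to 1.32 without liver 1. Wt1 (log2 4.47 ± 0.55, adjusted p = 0.0012), Gpm6a (at least 11.2-fold higher, adjusted p = 3.0e-04) and Upk3b (at least 13.6-fold higher, adjusted p = 0.011) were among them. Of the liver mesenchyme genes, 2 of 16 were higher and 0 lower (8 and 1 within the list). The list's relative median was 0.97, with adjusted p = 0.0095 and adjusted p = 0.18 with an estimated correlation. Colec11 (log2 3.20 ± 0.40, adjusted p = 0.0012) and Hlx (log2 1.59 ± 0.27, adjusted p = 0.0068, lost with quantile scaling) were the higher ones. Of the contractile and smooth muscle genes, 4 of 14 were higher and 0 lower (6 and 0 within the list). The relative median was 1.0, with adjusted p = 1.9e-06 and adjusted p = 0.18 with an estimated correlation. Myh11 (log2 3.13 ± 0.44, adjusted p = 0.0025) and Actg2 (log2 2.71 ± 0.43, adjusted p = 0.0050) were among them. Of the hepatocyte markers, 1 of 15 were higher and 0 lower (1 and 0 within the list). As a group they had a relative median of -1.72, with adjusted p = 0.14. Trf (log2 2.83 ± 0.42, adjusted p = 0.0030) was the higher one.

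In liver, 66.5% of the calls were higher, against 83.6% with normexp, 83.4% with quantile scaling, 41% with 13 arrays, 18.7% with array weights and 80.4% with only probes bright on all arrays. For liver, the slide block gave 302 genes, 280 of them shared. All 358 genes kept direction on slides 1, 2 and 3. In liver, 523 passed on the 13 arrays with normexp, 244 of them shared in direction and 0 opposite. Without heart 1, liver 1, liver 2 and skin 2, the count was 1018, 166, 150 and 233. Of the 43 followed genes, 0, 20, 20 and 1 then lost the call (at most 8 without any other array). The complement genes lost the list call without heart 1, heart 2 or liver 2.

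**Figure D4:**
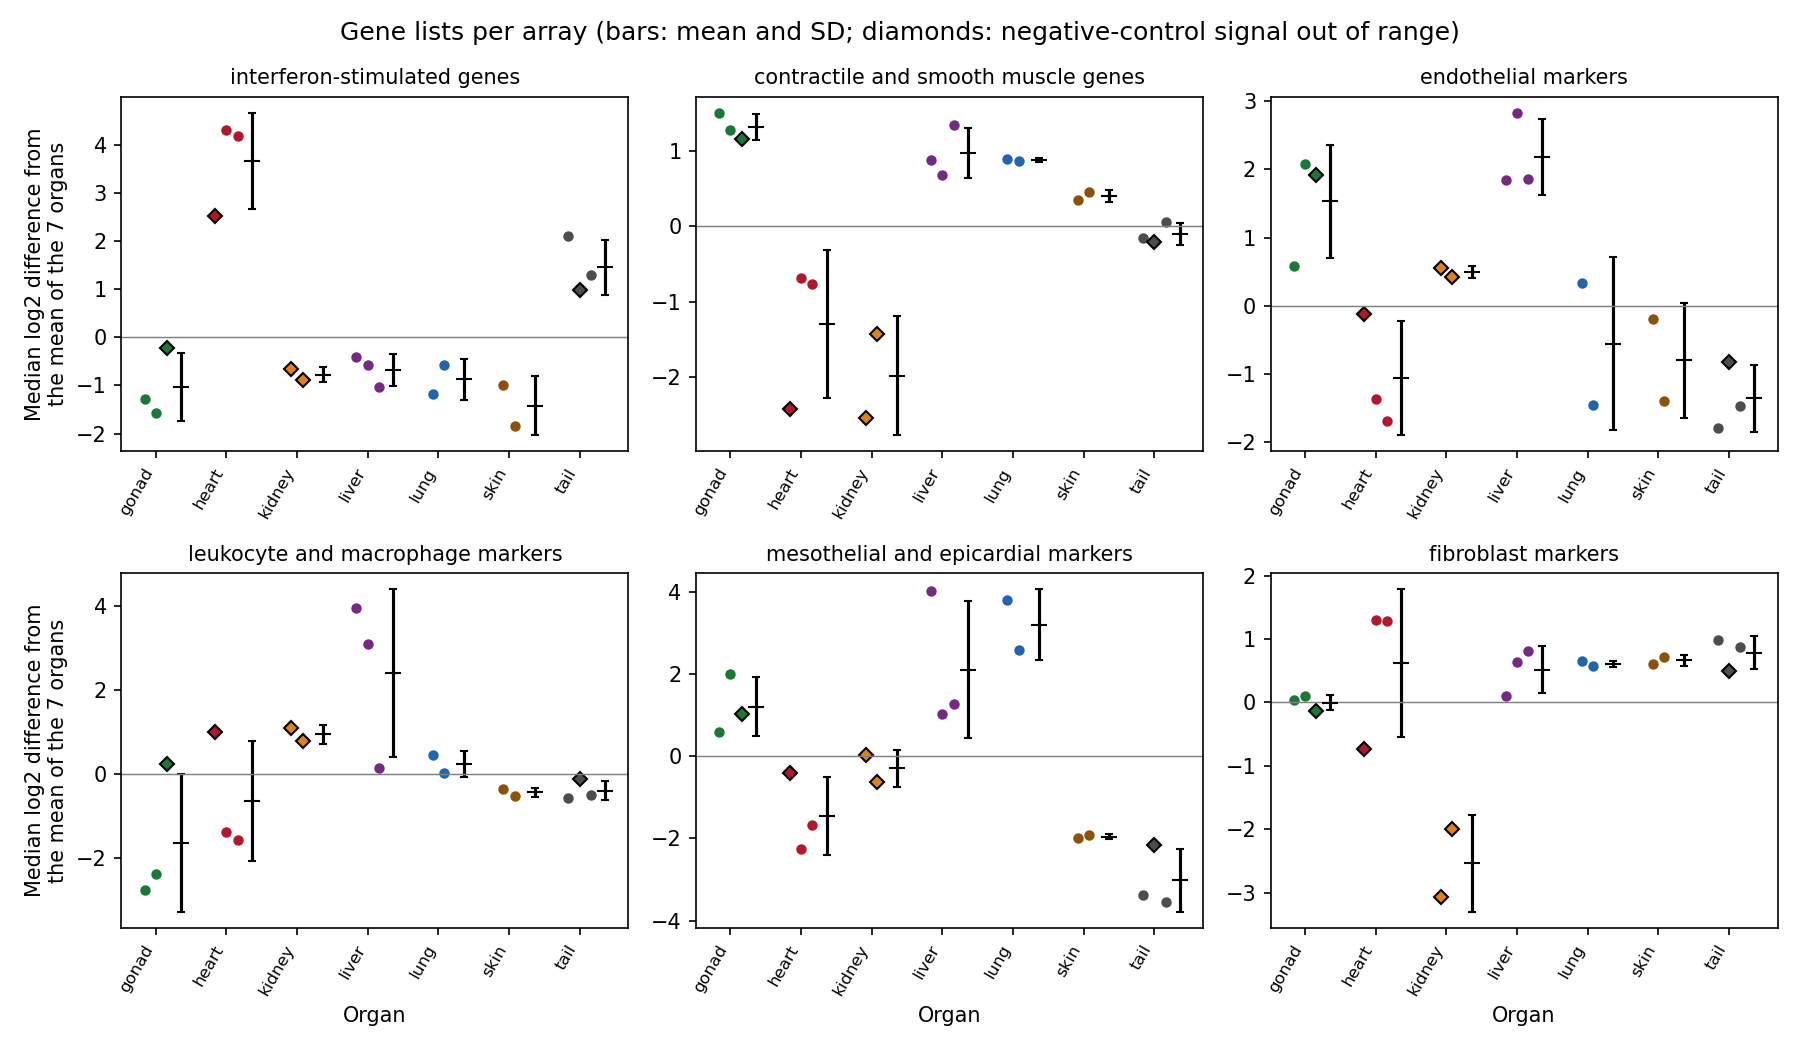
Median log2 difference from the mean of the 7 organs (vertical axis) of 6 gene lists on each of 18 arrays (points) by organ (horizontal axis), with the organ mean and SD as bars. The interferon-stimulated genes lie at 2.51, 4.31 and 4.17 on the heart arrays, and the endothelial markers at 1.85, 2.83 and 1.86 on the liver arrays.

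Lung fibroblasts (n = 2 arrays against 16) differed in 105 genes, 81 higher and 24 lower. The BMP antagonist Grem1 (at least 31.9-fold higher, adjusted p = 4.4e-04), the smooth muscle repressor Prdm6 (log2 4.56 ± 0.32, adjusted p = 2.2e-05), the integrin Itga8 (log2 4.37 ± 0.68, adjusted p = 0.012, lost with quantile scaling and the value table), and the chloride channel Ano1 (log2 3.35 ± 0.44, adjusted p = 0.0052, lost with quantile scaling) were higher. So were Frmd5 (at least 18.6-fold higher, adjusted p = 0.022), Hsd3b1 (at least 12.7-fold higher, adjusted p = 0.0052) and Cpb1 (at least 20.9-fold higher, adjusted p = 0.017, lost with the slide block) and the mineralization inhibitor Mgp (log2 3.18 ± 0.62, adjusted p = 0.039, lost with the slide block and 13 arrays). Syt13 (log2 -4.22 ± 0.60, adjusted p = 0.0078, lost with quantile scaling) and Rarres2 (log2 -2.28 ± 0.32, adjusted p = 0.0075) were lower, the second being the precursor of the chemoattractant chemerin.

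Of the mesothelial and epicardial markers, 4 of 12 were higher and 0 lower (9 and 0 within the list). Together their relative median was 3.58, with adjusted p = 3.1e-13 and adjusted p = 0.035 with an estimated correlation. Lrrn4 (at least 25.5-fold higher, adjusted p = 0.0078), Gpm6a (at least 17.6-fold higher, adjusted p = 8.2e-04) and Wt1 (log2 4.34 ± 0.66, adjusted p = 0.011, lost with quantile scaling) were among them. Of the lung mesenchyme genes, 2 of 15 were higher and 0 lower (5 and 0 within the list). Over the list, the relative median was 0.88, with adjusted p = 4.4e-05 and adjusted p = 0.055 with an estimated correlation. The T-box factors Tbx2 (log2 1.88 ± 0.31, adjusted p = 0.016) and Tbx3 (log2 1.82 ± 0.33, adjusted p = 0.027, lost with quantile scaling, the slide block and the value table) were the higher ones. Tbx3 turned to -0.29 with the value table of 19 samples. Of the contractile and smooth muscle genes, 1 of 14 were higher and 0 lower (5 and 0 within the list). As a whole, their relative median was 0.95, with adjusted p = 2.3e-05 and adjusted p = 0.23 with an estimated correlation. Mylk (log2 2.10 ± 0.35, adjusted p = 0.017, lost with quantile scaling and the slide block) was the higher one. Of the lung epithelial markers, 0 of 13 were higher and 0 lower (0 and 0 within the list), 0 and 0 at an unadjusted limma p under 0.05. Across the list, the relative median was -0.17, with adjusted p = 0.68. In lung, 77.1% of the calls were higher, against 64.1% with 13 arrays, 66.8% with 13 arrays and normexp, 24.3% with array weights and 88.3% with only probes bright on all arrays. For lung, the slide block gave 57 genes, 55 of them shared. All 105 genes kept direction on slides 1 and 2. In lung, 355 passed on the 13 arrays with normexp, 92 of them shared in direction and 0 opposite. Without heart 1, kidney 1, lung 1, lung 3, skin 1, skin 2, tail 1, tail 2 and tail 3, the count was 622, 69, 3, 4, 59, 61, 60, 68 and 61. Of the 29 followed genes, 0, 6, 27, 26, 7, 6, 6, 6 and 5 then lost the call (at most 3 without any other array).

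Skin fibroblasts (n = 2 arrays against 16) differed in 274 genes, 144 higher and 130 lower. The keratins Krt17 (at least 189-fold higher, adjusted p = 0.0051) and Krt14 (log2 5.65 ± 0.74, adjusted p = 0.0021), the epithelial serpin Serpinb5 (at least 62.1-fold higher, adjusted p = 0.013), and the gap junction gene Gjb2 (log2 5.80 ± 0.54, adjusted p = 2.7e-04) were higher. So were the homeobox factor Irx1 (log2 7.63 ± 0.83, adjusted p = 5.0e-04) and Lrrc15 (at least 112-fold higher, adjusted p = 2.7e-04) and Rpl39l (log2 7.33 ± 1.05, adjusted p = 0.0035). Calca (at least 3.77-fold lower, adjusted p = 9.9e-04, lost with mean of probes), Tox (at least 4.23-fold lower, adjusted p = 0.0034, lost with the value table) and Ecrg4 (log2 -3.56 ± 0.68, adjusted p = 0.018, lost with the slide block) were lower, and another probe of Calca gave 0.98.

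Of the keratinocyte markers in skin, 2 of 13 were higher and 0 lower (3 and 0 within the list). In all, their relative median was 0.62, with adjusted p = 0.0045 and adjusted p = 0.43 with an estimated correlation, the median moving to 0.98 without skin 2. Krt17 and Krt14 were the passing ones. Of the dermal and limb mesenchyme regulators, 2 of 14 were higher and 0 lower (5 and 0 within the list). Their relative median was 0.82, with adjusted p = 1.5e-04 and adjusted p = 0.061 with an estimated correlation. Tbx15 (log2 3.22 ± 0.57, adjusted p = 0.013) and Twist2 (log2 2.59 ± 0.56, adjusted p = 0.035, lost with normexp, quantile scaling, median scaling and the slide block) were among them. Of the chemokines and cytokines, 5 of 20 were higher and 0 lower (8 and 0 within the list). The list's relative median was 0.54, with adjusted p = 9.6e-04 and adjusted p = 0.18 with an estimated correlation, lost with 13 arrays and the floor covariate. Cxcl5 (log2 6.68 ± 1.26, adjusted p = 0.017), Il11 (log2 4.83 ± 0.52, adjusted p = 5.0e-04) and Cxcl14 (log2 4.39 ± 0.60, adjusted p = 0.0027) were among them. Of the mesothelial and epicardial markers, 0 of 12 were higher and 5 lower (0 and 6 within the list). The relative median was -2.65, with adjusted p = 2.5e-13 and adjusted p = 0.035 with an estimated correlation. Wt1 (log2 -4.76 ± 0.66, adjusted p = 0.0028) and Lrrn4 (at least 8.35-fold lower, adjusted p = 0.0058) were among them. Of the proliferation genes, 0 of 20 were higher and 0 lower (14 and 0 within the list), 15 and 0 at an unadjusted limma p under 0.05. As a group they had a relative median of 0.91, with adjusted p = 4.5e-07 and adjusted p = 0.52 with an estimated correlation. Of the interferon-stimulated genes, 0 of 17 were higher and 1 lower (0 and 10 within the list). Together their relative median was -2.00, with adjusted p = 2.0e-14 and adjusted p = 0.18 with an estimated correlation. In skin, 52.6% of the calls were higher, against 83.8% with 13 arrays, 46.1% with 13 arrays and normexp, 77.9% with the background term, 72.3% with the floor covariate, 70.2% with the value table, 81.1% with array weights, 70.2% with the value table of 18 samples, 66.3% without heart 1, 77.8% without skin 1 and 91.7% without skin 2. For skin, the slide block gave 198 genes, 188 of them shared. All 274 genes kept direction on slides 1 and 2. In skin, 1140 passed on the 13 arrays with normexp, 255 of them shared in direction and 0 opposite. Without heart 1, skin 1 and skin 2, the count was 1243, 18 and 12. Of the 28 followed genes, 0, 22 and 24 then lost the call (at most 3 without any other array). The Hox groups 9 to 13 lost the list call without gonad 1, heart 2, heart 3 or liver 1.

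Tail fibroblasts (n = 3 arrays against 15) differed in 1237 genes, 805 higher and 432 lower. Among the higher genes were the matrix genes Thbs4 (at least 3670.0-fold higher, adjusted p = 4.3e-06), Cilp (at least 848-fold higher, adjusted p = 2.3e-06) and Comp (log2 7.60 ± 0.59, adjusted p = 6.9e-06), and lubricin, Prg4 (log2 6.90 ± 0.72, adjusted p = 5.2e-05). Another probe of Prg4 gave log2 1.07. Also higher were the carbonic anhydrase Car3 (at least 678-fold higher, adjusted p = 1.6e-05), the Wnt modulator Sfrp2 (log2 7.37 ± 0.80, adjusted p = 7.2e-05), the opioid precursor Penk (log2 6.71 ± 0.56, adjusted p = 9.4e-06), and Abi3bp (log2 7.19 ± 0.83, adjusted p = 1.1e-04). Serpinb6b (log2 -7.13 ± 0.48, adjusted p = 2.3e-06) and Plac8 (log2 -6.30 ± 0.50, adjusted p = 7.0e-06) and the Notch target Heyl (at least 13.9-fold lower, adjusted p = 7.9e-05) were lower.

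Of the interferon-stimulated genes in tail, 9 of 17 were higher and 0 lower (11 and 0 within the list). Over the list, the relative median was 1.23, with adjusted p = 4.5e-07 and adjusted p = 0.43 with an estimated correlation. Ifit1 (log2 3.20 ± 0.55, adjusted p = 0.0024) and Ifit3 (log2 3.11 ± 0.53, adjusted p = 0.0024) were among them. Of the dermal and limb mesenchyme regulators, 5 of 14 were higher and 0 lower (5 and 0 within the list). As a whole, their relative median was 0.62, with adjusted p = 8.2e-04 and adjusted p = 0.10 with an estimated correlation. Prrx2 (log2 3.07 ± 0.50, adjusted p = 0.0015), Tbx15 (log2 2.72 ± 0.48, adjusted p = 0.0029) and Twist1 (log2 1.95 ± 0.29, adjusted p = 9.1e-04) were among them. Of the mesothelial and epicardial markers, 0 of 12 were higher and 9 lower (1 and 9 within the list). Across the list, the relative median was -3.83, with adjusted p = 6.9e-16 and adjusted p = 0.035 with an estimated correlation. Wt1 (log2 -6.80 ± 0.55, adjusted p = 8.7e-06) and Aldh1a2 (log2 -4.53 ± 0.46, adjusted p = 4.3e-05) led them. Of the endothelial markers, 1 of 16 were higher and 5 lower (1 and 6 within the list). In all, their relative median was -1.87, with adjusted p = 4.6e-10 and adjusted p = 0.15 with an estimated correlation. Robo4 (at least 21.4-fold lower, adjusted p = 6.9e-04) and Cdh5 (log2 -3.31 ± 0.56, adjusted p = 0.0021) were among them. Of the proliferation genes, 0 of 20 were higher and 1 lower (0 and 4 within the list). Their relative median was -1.27, with adjusted p = 5.5e-10 and adjusted p = 0.42 with an estimated correlation. Bub1 (log2 -1.40 ± 0.31, adjusted p = 0.015, lost with median scaling) was the passing one. Beside Sfrp2, the Wnt antagonist Dkk2 (log2 5.82 ± 0.49, adjusted p = 9.4e-06) was higher and Sfrp4 (at least 9.96-fold lower, adjusted p = 1.0e-04) lower. Col10a1 (log2 2.84 ± 0.63, adjusted p = 0.014) and the germ cell RNA helicase Ddx4 (at least 38.2-fold higher, adjusted p = 2.7e-06) were higher. In tail, 65.1% of the calls were higher, against 75.8% with 13 arrays, 46.0% with 13 arrays and normexp and 78.5% with array weights. For tail, the slide block gave 1055 genes, 1043 of them shared. All 1237 genes kept direction on slides 1, 2 and 3. In tail, 1369 passed on the 13 arrays with normexp, 910 of them shared in direction and 0 opposite. Without heart 1, tail 1, tail 2 and tail 3, the count was 1984, 544, 744 and 602. Of the 45 followed genes, 0, 8, 6 and 8 then lost the call (at most 2 without any other array).

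Skin set directly against tail (n = 2 arrays against 3) differed in 559 genes, 232 higher in skin and 327 lower. Higher in skin were the keratins Krt17 (log2 9.19 ± 1.43, adjusted p = 0.0033) and Krt14 (log2 5.92 ± 0.90, adjusted p = 0.0030), Serpinb5 (at least 59.8-fold higher, adjusted p = 0.0072), and the cornified envelope genes Lce3a (at least 16.1-fold higher, adjusted p = 6.6e-04) and Lce1f (at least 16.9-fold higher, adjusted p = 0.0077). The acute phase gene Saa3 (log2 7.82 ± 1.30, adjusted p = 0.0047) was higher as well. Of the keratinocyte markers, 2 of 13 were higher and 0 lower (4 and 0 within the list). The list's relative median was 0.59, with adjusted p = 0.0022 and adjusted p = 0.39 with an estimated correlation, the median moving to 0.30 without tail 1 and 0.88 without tail 2. Lower in skin were Thbs4 (log2 -10.07 ± 1.30, adjusted p = 0.0013), Hoxb13 (log2 -9.50 ± 1.15, adjusted p = 7.7e-04) and Car3 (log2 -8.93 ± 1.26, adjusted p = 0.0020) and Calca (at least 37.6-fold lower, adjusted p = 4.2e-05, lost with mean of probes) and Ddx4 (at least 45.4-fold lower, adjusted p = 4.2e-05), with 0.18 from another probe of Calca.

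Of the interferon-stimulated genes, 0 of 17 were higher and 9 lower (0 and 13 within the list). The relative median was -2.61, with adjusted p = 8.4e-17 and adjusted p = 0.15 with an estimated correlation. Ifit3 (log2 -5.40 ± 0.77, adjusted p = 0.0020) and Usp18 (log2 -4.08 ± 0.70, adjusted p = 0.0060) were among them. Of the proliferation genes, 1 of 20 were higher and 0 lower (16 and 0 within the list). As a group they had a relative median of 1.91, with adjusted p = 3.3e-14 and adjusted p = 0.26 with an estimated correlation. Bub1 (log2 2.23 ± 0.45, adjusted p = 0.015, lost with median scaling) was the passing one. Among fibroblast markers, Cd34 (log2 -4.80 ± 0.68, adjusted p = 0.0020) and Pi16 (log2 -2.88 ± 0.70, adjusted p = 0.042, lost with median scaling and the slide block) were lower and Postn (log2 2.91 ± 0.67, adjusted p = 0.031, lost with median scaling), a matrix protein, higher. With only skin and tail arrays, 2229 genes passed. Of the 559 calls, 41.5% were higher, against 50.2% with quantile scaling, 53.1% with 13 arrays and 50.5% with the floor covariate. It was 50.2% with array weights, 50.4% with only these arrays and 52.5% without heart 1. For skin against tail, the slide block gave 397 genes, 392 of them shared. All 559 genes kept direction on slides 1 and 2. In skin against tail, 1845 passed on the 13 arrays with normexp, 526 of them shared in direction and 0 opposite. Without heart 1, skin 1, skin 2, tail 1, tail 2 and tail 3, the count was 1885, 110, 77, 252, 310 and 271. Of the 29 followed genes, 0, 14, 20, 7, 7 and 7 then lost the call (at most 5 without any other array).

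Skin and tail together, set against the 5 internal organs (n = 5 arrays against 13), differed in 837 genes, 504 higher and 333 lower. Higher at the body surface were Cilp (at least 308-fold higher, adjusted p = 2.5e-06), Irx1 (log2 7.03 ± 0.59, adjusted p = 1.8e-05) and Il1rl1 (at least 96.1-fold higher, adjusted p = 1.0e-07), the stem cell receptor Lgr5 (at least 32.8-fold higher, adjusted p = 8.7e-05), the tendon gene Tnmd (log2 4.98 ± 0.55, adjusted p = 1.0e-04), and the hedgehog antagonist Hhip (log2 4.67 ± 0.60, adjusted p = 3.5e-04). Lower were Gata4 (at least 40.8-fold lower, adjusted p = 7.6e-07) and Wt1 (log2 -6.94 ± 0.47, adjusted p = 3.2e-06), factors of internal mesoderm, and Clca3a1 (log2 -5.61 ± 0.52, adjusted p = 3.3e-05) and Serpinb6b (log2 -5.55 ± 0.40, adjusted p = 4.4e-06).

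Of the dermal and limb mesenchyme regulators, 6 of 14 were higher and 0 lower (7 and 0 within the list). Together their relative median was 0.94, with adjusted p = 3.8e-06 and adjusted p = 0.035 with an estimated correlation. Tbx15 (log2 3.57 ± 0.41, adjusted p = 1.3e-04), Prrx2 (log2 2.81 ± 0.42, adjusted p = 0.0011) and Msx2 (log2 1.92 ± 0.32, adjusted p = 0.0024) were among them. Of the mesothelial and epicardial markers, 0 of 12 were higher and 9 lower (1 and 9 within the list). Over the list, the relative median was -4.12, with adjusted p = 3.5e-22 and adjusted p = 0.015 with an estimated correlation. Lrrn4 (at least 16.2-fold lower, adjusted p = 4.9e-05) and Gpm6a (at least 8.37-fold lower, adjusted p = 4.4e-06) were among them. Of Hox groups 9 to 13, 7 of 14 were higher and 0 lower (7 and 0 within the list). As a whole, their relative median was 2.39, with adjusted p = 1.0e-04 and adjusted p = 0.52 with an estimated correlation. Hoxb13 (at least 64.9-fold higher, adjusted p = 6.4e-05), Hoxc9 (log2 4.27 ± 0.71, adjusted p = 0.0024) and Hoxc13 (log2 4.04 ± 0.36, adjusted p = 2.9e-05) were among them. Hoxb13, Hoxc13, Cilp and Dkk2 were higher in tail than in each other organ, skin included. Of the heart development regulators, 1 of 13 were higher and 3 lower (1 and 4 within the list). Across the list, the relative median was -1.05, with adjusted p = 1.2e-05 and adjusted p = 0.044 with an estimated correlation, the list's own median going from -0.60 to 0.02 with 13 arrays. Gata6 (log2 -2.73 ± 0.32, adjusted p = 1.5e-04) and Tbx2 (log2 -1.74 ± 0.22, adjusted p = 3.3e-04) were lower and Tbx3 (log2 1.37 ± 0.24, adjusted p = 0.0031, lost with the value table) higher. The chemokines Cxcl5 (log2 6.12 ± 0.90, adjusted p = 9.6e-04) and Ccl7 (log2 3.79 ± 0.42, adjusted p = 1.0e-04) and the Wnt modulators Sfrp2 (log2 5.01 ± 0.68, adjusted p = 5.2e-04) and Dkk2 (log2 4.20 ± 0.41, adjusted p = 5.2e-05) were higher. Kidney development regulators, lung mesenchyme genes, contractile genes and simple epithelial markers passed as lower (adjusted p = 0.048, 0.045, 0.038 and 0.019). Their relative medians were 0.14, -0.07, -0.25 and 0.01. With an estimated correlation they gave adjusted p = 0.19, 0.38, 0.65 and 0.70. Their own means were -0.44, 0.16, -0.19 and -0.13. In this comparison, 60.2% of the calls were higher, against 87.0% with 13 arrays, 45.9% with 13 arrays and normexp, 85.3% with the background term, 84.8% with array weights and 70.4% with only probes bright on all arrays. For skin and tail together, the slide block gave 777 genes, 747 of them shared. Of the 837 genes, 837, 837 and 822 kept direction on slides 1, 2 and 3. In skin and tail together, 1060 passed on the 13 arrays with normexp, 581 of them shared in direction and 0 opposite. Without heart 1, skin 1 and skin 2, the count was 1265, 459 and 377. Of the 47 followed genes, 0, 2 and 6 then lost the call (at most 1 without any other array).

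Over the 33 lists and 9 comparisons, 122 of the list tests passed, and 14 with an estimated correlation. For each list, the number of the 9 comparisons in which it passed stands first, then in brackets how many of these were higher and how many held with an estimated correlation. For Hox they were Hox groups 1 to 4 6 (3, 2), Hox groups 5 to 8 4 (3, 1) and Hox groups 9 to 13 8 (5, 0). For organ identity they were heart development regulators 4 (1, 1), kidney development regulators 2 (0, 1), liver mesenchyme genes 4 (1, 0), lung mesenchyme genes 3 (1, 0), gonad somatic genes 4 (1, 2) and dermal and limb mesenchyme regulators 4 (3, 1). For fibroblast state they were fibroblast markers 4 (3, 0), collagens 2 (1, 0), matrix proteases and inhibitors 3 (2, 0), contractile and smooth muscle genes 7 (3, 1), Wnt ligands and antagonists 1 (0, 0), proliferation genes 7 (5, 0), interferon-stimulated genes 7 (2, 1), chemokines and cytokines 3 (2, 0) and complement genes 3 (2, 0). For other cell types they were leukocyte and macrophage markers 6 (1, 0), endothelial markers 7 (3, 0), pericyte markers 0 (0, 0), simple epithelial markers 6 (2, 0), keratinocyte markers 3 (2, 0), hepatocyte markers 2 (1, 0), cardiomyocyte markers 2 (1, 0), kidney tubule markers 2 (1, 0), lung epithelial markers 1 (0, 0), skeletal muscle markers 2 (1, 0), germ cell markers 4 (1, 0), mesothelial and epicardial markers 7 (3, 4), Schwann, neural crest and melanocyte markers 1 (0, 0), adipocyte markers 1 (0, 0) and cartilage and bone genes 2 (0, 0).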

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

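The tests of lung replicate 2, of other cell types in kidney, of the signal before scaling, of leukocytes and high background for the heart genes, and of the liver markers were chosen after the results were seen.

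Lung replicate 2 enters only fits of the deposited value table, and whether it carries a lung signal stays open. Of the 81 genes higher in the other 2 lung arrays, 77 (95.1%) also lay above the mean of the other organs in it, against 72 in the array of another organ with the most. All 24 genes lower in lung lay below, with no other array compared. The correlation of its values across genes, which are not independent replicates, was 0.933 with lung 1, 0.932 with lung 3 and at most 0.925 with an array of another organ, while lung 1 and lung 3 correlated at 0.995. Of the 10 largest genes higher in lung by the naming rule, 9 lay above, and Itga8 was at -1.75. The cause was not tested.

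Genes that other arrays put at the floor carried signal on gonad 3, heart 1, kidney 1, kidney 2 and tail 2, and the first principal component, 68.0% of the variance, set these 5 apart. Genomic DNA in the labelled RNA would raise probes of autosomal regions more than those of the X chromosome of male mice, but dim X-linked probes (118) less dim autosomal probes (2922) differed by 0.023 from the 13 other arrays (each of the 5 between -0.06 and 0.16, the 13 between -0.04 and 0.05), which argues against it. Cells of other types in the kidney samples would raise few other organs' markers. Yet 69 markers of 5 other lists had a median of 2.63, above the 2.20 of the tubule markers, and of 0.55 on the 5 arrays alone. This argues against such cells as the source of the raised signal of these 69 markers only. Epithelial cells in the kidney samples stay open. On the 5 arrays alone, 5 of 14 simple epithelial markers were higher and 0 lower. Of 19 fibroblast markers there, 0 were higher and 8 lower. Normexp and quantile normalization took the median of the 69 markers to 0.28, which met the test written for scaling as the source. Yet before scaling the lowest of the 5 arrays stood 1.71 log2 above the highest of the 13 in dim probes. The signal was therefore there before scaling, and its source is open. Apart from cells of other types in kidney, no biological explanation was tested.

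Interferon-stimulated genes were higher in all 3 heart samples. Leukocytes carried along would bring their own markers, whose median less the mean of the 7 organs was -1.37 or lower on heart 2 and 3 and 1.01 on heart 1, where the raised floor keeps it open (levels relative to the 75th percentile: Itgam 3.67, Csf1r 1.57, Lyz2 -1.29). On the 13 other arrays with normexp, the median of the interferon genes was 4.14. Within slides it was 4.81, 3.34 and 4.38, so background and slide are argued against. Hepatocyte markers also lay low on heart 2 and 3 (-1.17, -1.38), so leukocytes stay open. A difference in the heart fibroblasts and a response to something in these cultures stay open as untested.

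In liver 7 of 16 endothelial and 6 of 16 leukocyte and macrophage markers passed as higher, the lists being lost with an estimated correlation (adjusted p = 0.15 and 0.32). Of the markers well above background on all liver arrays, 27 of 31 (87.1%) lay at least 0.5 log2 above the median of all genes, but these were picked by their liver level from the lists in which the pattern was seen, so the share decides nothing and cells carried along stay open. Relative to the 75th percentile, the liver means of Egfl7 and Robo4 were 6.71 and 3.61, and those of Itgam, Csf1r and Ptprc 5.04, 3.63 and -3.31, while C1qa, C1qb and C1qc also stand in the complement list and the labels name no sort. A change in the fibroblasts themselves stays open as untested. The macrophage list's median was 3.96, 3.10, 0.15 in liver 1, 2 and 3.

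Each regrouping was of the 18 arrays into groups of the same sizes, and 100 were drawn, the real one included. The real gonad count of 573 was not reached by another (highest other 269). Nor was that of skin and tail against the internal organs, 837 (highest other 15). In each, 1 of 100 was thus as large, the lowest share that 100 regroupings can give. Mixed organs and backgrounds also widen the spread within regrouped groups, and the other regroupings had a median of 0 genes. For heart (742), liver (358) and tail (1237), 4, 3 and 3 of 100 were as large, the real one included, and the highest others gave 13840, 15740 and 13920 genes. Those larger groups held at least 3, 3 and 2 high-background arrays, which shows a structure of the samples. An exclusion of chance is not claimed for any of these comparisons.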

How the results depend on the processing

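The tests that leave out the 5 high-background arrays, keep only these, or adjust for them or for the array floor were chosen after the data were seen, and the other alternatives were chosen before the data were examined. Of the values of the followed genes, 6187 kept direction and side of the threshold and 433 kept direction but no longer passed. The 1 that reversed was Tbx3 in lung (-0.29 with the deposited value table of 19 samples). The cause was not tested. Pooling all other arrays accounts for 182 of the 433 and an adjusted p under 0.01 for 84. Of the gene list results followed, 811 stayed and 123 no longer passed, 55 of these with an estimated correlation and 20 with fry. Leaving out 1 array ended 504 gene calls and 21 list calls and left 5724 and 1203 as they were.

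Counts that moved by more than 1.5 times are given by setting, with organ names standing for that organ versus the mean of the other 6 organs. Without the 5 high-background arrays there is no kidney, so there an organ is set against 5 others, skin and tail against 4, and a gene has to be higher than in 5. The counts without an alternative were gonad 573, heart 742, kidney 15334, liver 358, lung 105, skin 274, tail 1237, skin versus tail 559, skin and tail versus the 5 internal organs 837, the F test 6696, genes higher in 1 organ 286 and gene list tests 122. With array weights estimated by limma: gonad 7348, heart 4383, liver 3782, lung 3171, skin 3585, tail 4080, skin versus tail 2850, skin and tail versus the 5 internal organs 4245, the F test 18344 and genes higher in 1 organ 4500. At an adjusted p under 0.01: gonad 279, heart 427, kidney 8412, liver 136, lung 21, skin 79, tail 663, skin versus tail 231, skin and tail versus the 5 internal organs 498, the F test 1750 and genes higher in 1 organ 68. With all other arrays pooled as one group: gonad 54, heart 127, liver 1, lung 0 (317 by limma at an unadjusted p under 0.05), skin 5 and tail 282. With normexp and quantile normalization: kidney 7840, lung 247, skin 464, skin versus tail 1169 and genes higher in 1 organ 1506. With quantile normalization alone: kidney 9630, lung 185, skin 428, skin versus tail 1022 and genes higher in 1 organ 917. With scaling to the median of detected probes: skin 177, skin versus tail 338 and the F test 4003. With probes well above background on all arrays, which are fewer: kidney 9188. With a variance trend and robust eBayes: lung 171. With the slide as a block: lung 57 and the F test 4384. With the replicate number as a block: lung 46, skin 166, skin versus tail 363, the F test 3263 and genes higher in 1 organ 175. With the deposited value table of 19 samples: lung 492, the F test 11730 and genes higher in 1 organ 783. On its 18 samples: lung 204, the F test 10827 and genes higher in 1 organ 654. On only the skin and tail arrays: skin versus tail 2229. With camera and an estimated correlation: gene list tests 14. With fry: gene list tests 76.

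Without the 5 high-background arrays: gonad 4086, heart 1642, liver 1082, lung 401, skin 4609, tail 4107, skin versus tail 2367, skin and tail versus the 5 internal organs 5395 and genes higher in 1 organ 725. Without them and with normexp and quantile normalization: gonad 980, lung 355, skin 1140, skin versus tail 1845 and genes higher in 1 organ 641. With high background as a term: gonad 2449, heart 1115, kidney 3008, lung 213, skin 1746, tail 2252, skin versus tail 1388 and skin and tail versus the 5 internal organs 3488. With the array floor as a covariate: gonad 1102, heart 1338, kidney 3820, liver 549, lung 309, skin 3047, tail 3132, skin versus tail 2004, skin and tail versus the 5 internal organs 3124 and genes higher in 1 organ 541. On only the 5 high-background arrays: kidney 358. The stricter threshold and the fits on fewer probes or arrays differ by construction, and for the other moves the cause was not tested.

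Leaving out each array in turn gave these ranges: gonad 213 (without gonad 1) to 2534 (without gonad 3), heart 448 (without heart 3) to 2068 (without heart 1), kidney 415 (without kidney 1) to 16140 (without heart 1) and liver 150 (without liver 2) to 1018 (without heart 1). For the next organs they were lung 3 (without lung 1) to 622 (without heart 1), skin 12 (without skin 2) to 1243 (without heart 1) and tail 544 (without tail 1) to 1984 (without heart 1). For the remaining counts they were skin versus tail 77 (without skin 2) to 1885 (without heart 1), skin and tail versus the 5 internal organs 377 (without skin 2) to 1265 (without heart 1), the F test 1797 (without kidney 1) to 16081 (without heart 1), genes higher in 1 organ 53 (without skin 2) to 1835 (without heart 1) and gene list tests 115 (without heart 1) to 130 (without liver 1). Where an organ was left with 1 array, its spread is assumed to be that of the other organs. Kidney has no contrast on the 13 arrays. List tests with the replicate number as a random block were not run, since camera uses none. Of 18 arrays, 7 were closest to one of their own number, and the estimated correlation within a number was -0.07. Pairing stays open, since gonad 3 and heart 1, of high background, correlated at 0.90. Signal over background was not varied on its own. In simulated data with the spread of the 18 arrays, 34% of genes shifted by 1.5 log2 and 80% by 4 were recovered in gonad. In lung it was 10% and 68%, in kidney 16% and 84%. With the spread of the 13 arrays but 7 organs, unlike their own fit, gonad gave 98% and 100%.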

Other observations

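The sex of the mice is not given by the labels. The Y-linked genes Ddx3y, Eif2s3y and Uty were detected on all 18 arrays and Kdm5d on 9. Xist, which female cells express from the inactive X, was detected on 2 and ranged from -7.53 to -2.65 log2 relative to the 75th percentile, highest on liver 2.

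Each other probe of a named gene gives a check within the arrays. Of 637 gene and comparison pairs, 98 had another probe, with 112 values, of which 13 had the opposite sign.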
